A study of Homo sapiens with 24 samples.

How the data were processed

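RNA of TF-1 cells, an established human erythroleukaemia line, was compared on 24 Agilent 2-colour arrays of 62976 spots. Cells grew with erythropoietin (EPO, 10 U/mL) or with GM-CSF (5 ng/mL), with or without TNF (20 ng/mL) from 24 h after seeding, and were stopped at 0, 6, 24 or 48 h. RNA was isolated with TRIzol, cleaned on columns, and 200 ng per reaction was amplified and labelled with Cy5 or Cy3. Each array carried a pair of RNAs from the same replicate (A, B or C), and the arrays formed an interwoven loop over 10 RNAs on 3 slides. RNAs are written as E (EPO), ET (EPO plus TNF), G (GM-CSF) or GT (GM-CSF plus TNF) with the hour, as in E_6.

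Per the file headers, the spot and local background signals of both channels are median pixel intensity values from Agilent Feature Extraction 11.5.1.1, without normalization, and the processed signals are intensity values after that program's background subtraction and dye normalization. The 0 or 1 flags per spot and channel (other unit) come from the same program, per the file headers. The values of the authors are a log2 ratio of Cy5 over Cy3 per probe and array, made with limma per the labels, without a stated version or steps. The deposited log2 ratios had a median near 0 on every array and correlated across probes with the ratios computed here, r from 0.90 to 0.99.

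The ratios were computed from the median spot and background intensities with limma 3.58.1 in R 4.3.3: background correction by normexp with an offset of 50, loess within each array, and the mean of the unflagged spots of a probe. Control spots (1439) and 216 probes without an unflagged spot on some array were left out. Probes were kept when at least 0.5 of the channels of at least 1 RNA were well above background, which left 36313 of 56220 probes. The files give accessions without gene names, so symbols were taken by RefSeq accession from a gene table of assembly GRCh38.p14. This named 24809 probes, 24794 of the 25635 with an NM or NR accession. No coordinates are given, because the array design uses hg19. The brightest probe stood for each gene or identifier, which gave 31503 features, 15657 of them with a symbol.

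All arrays were fitted together in limma with a column per RNA and a dye term per probe. Arrays that shared an RNA extract were given a shared variance, as a ratio of 0.0574 to the array variance, estimated by restricted maximum likelihood over all probes. The fit had 14 residual and 6.46 prior degrees of freedom. Each of 15 contrasts was adjusted by Benjamini-Hochberg at 0.05. Errors are moderated standard errors (SE), with n = 3 extracts per RNA. That n does not count the replicates that join both sides of a contrast. Within a replicate, arrays joined RNAs with TNF to those without in A and C only. They joined EPO at 0 h to later hours in EPO, and GM-CSF to EPO at 6 h, in B only. The errors and list tests of contrasts joined in B only do not measure how such a change varies between replicates. Differences of TNF effects were joined in all 3. The number of arrays limits the precision, with a median SE between 0.07 and 0.11 on the log2 scale. The replicate cancels within each array, so the design is paired by replicate. As a check on channel values averaged per extract, extracts of the same replicate that shared no array deviated together, with a median correlation across genes of 0.54 in A, 0.37 in B and 0.60 in C, against -0.29 between replicates. Pairs of B went as low as -0.16. Replicates A and C each sat on a single slide, so this check cannot tell a shared slide from a shared replicate. Deviations from the mean of 3 extracts lean negative between replicates by construction, so the -0.29 is not a separate comparison.

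On simulated data of the same design, 94.0% of changes of 0.5 on the log2 scale were recovered for TNF in EPO at 6 h and 77.6% at 48 h. Between 4.17% and 6.22% of simulated calls were false. The simulated data had the fitted variance ratio of 0.0574. These rates therefore say nothing about departures from that fit, such as a dye bias of a single replicate.

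Gene lists (19, with 585 entries) were written before the data were examined, and cover NF-kB feedback, cytokines, interferon response, antigen presentation, globins and haem, erythroid regulators, monocyte, megakaryocyte and stem cell markers, JAK-STAT5 targets, immediate early genes, cell cycle, p53, amino acid and ER stress, cholesterol, hypoxia, iron, named long non-coding RNAs, and lymphoid markers. Of the entries, 63 had no probe with that name and 30 did not pass the filter. Each list was tested on 8 contrasts with limma's camera (preset correlation 0.01, adjusted over all 152 tests), again with an estimated correlation, and with fry. Genes are named by a rule set at the same time. It takes, per contrast, the 6 largest rises and the 6 largest falls with a symbol among features past the threshold that moved the same way on every array comparing the pair directly (waived without such arrays), 2 unnamed long non-coding features each way, up to 4 members per list, any member of the globin, erythroid, NF-kB and JAK-STAT5 lists, and neighbours of PTTG1 within 500 kb in the gene table. The long non-coding class holds the features of custom probes with TCONS or Ensembl identifiers, since the files hold no lincRNA names.

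Alternatives were chosen before the data were examined: processed signals, median centring, scaling between arrays, other filters, the mean of all probes, no dye term or a dye term per slide, arrays as independent, separate channels, extract means with and without a replicate block, direct arrays only, the deposited ratios, a change of at least 1 on the log2 scale, and leaving out each replicate. Added after seeing the data were a dye term per scan or per replicate, and leaving out 1 or both of 2 arrays. Slide 1 was scanned apart from slides 2 and 3. Background correction had been planned on spot means and was run on spot medians, which the files hold.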

Results

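The measurements were log2 ratios between pairs of RNAs of TF-1 cells, a human erythroleukaemia line that grows on GM-CSF or EPO. The 24 arrays compared 10 RNAs, each with 3 extracts (replicates A, B and C) and with 4 to 6 channels. Pairs with and without TNF of the same hour shared an array in replicates A (slide 1) and C (slide 3), with opposite dyes, whereas replicate B held a loop of hours in EPO, another in EPO plus TNF, and links to the GM-CSF RNAs. The median net signal of an array was between 54.6 and 78.0 in Cy3 and between 85.6 and 122 in Cy5. The array of E_48 and E_6 in replicate A was an exception at 205 and 364. Between 29375 and 39017 probes were well above background in Cy3 on the other arrays. The question of the series, by its title, is how inflammatory mediators change long non-coding RNA in myeloid leukaemia. The labels do not say for how long the cells had been with EPO before 0 h.

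**Figure D1:**
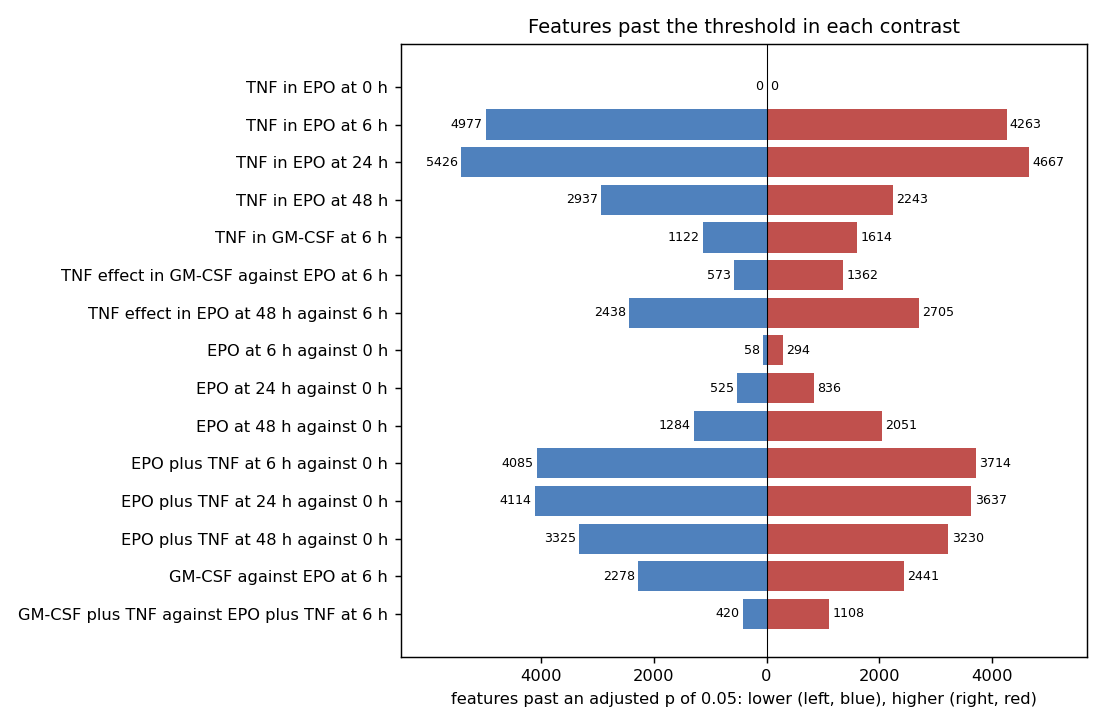
Features past an adjusted p of 0.05 in each of the 15 contrasts, with higher features to the right (red) and lower features to the left (blue). TNF in EPO at 24 h had the most, 4667 higher and 5426 lower, and TNF in EPO at 0 h had 0.

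At 0 h, the comparison of ET_0 with E_0 asks whether the arms differed when TNF was added. By limma, 0 of 31503 features passed the adjusted threshold, while 3727 had an unadjusted p under 0.05, which is 11.8% where chance gives 5%. The direct arrays went apart, with a correlation across genes (which are not independent replicates) of -0.46 between replicates A and C once both were written as TNF over no TNF. Their SDs were 0.30 in A and 0.16 in C. Without replicate C, 1578 features passed. Only arrays of A, all with TNF on Cy3, then joined RNAs with TNF to those without. A dye bias of A could thus give such a count. With a dye term for each replicate, 1 feature passed and 1996 had an unadjusted p under 0.05. TNF was on Cy3 on the direct arrays of A and on Cy5 on those of C. Such a term is thus hard to separate from the TNF effect, and fewer features with it can also mean lost precision.

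At 6 h with EPO, TNF changed 9240 features, 4263 higher and 4977 lower. Of these, 546 changed by at least 1 on the log2 scale, and 90.0% moved the same way on both direct arrays. Those arrays are part of the fit that chose the features, which favours such agreement. The count depends on how the dye bias is modelled: with a dye term per replicate it was 5319, of which 4776 were shared, and more were then higher (54.3%) than lower. With median centring 25.1% were higher, so the balance of directions is not settled. UBD rose by 7.25 ± 0.29 (SE, n = 3 extracts per RNA, adjusted p 6.77e-14). It was at 6.51 on the direct array of replicate A and 8.15 on that of C. No arrays of replicate B joined RNAs with TNF to those without. LTB rose by 5.32 ± 0.18, BIRC3 by 4.99 ± 0.16, TNFRSF9 by 4.17 ± 0.11, CD70 by 3.86 ± 0.10 and SPP1 by 3.75 ± 0.15. TNFRSF9 was well above background in only 3 of 6 channels of E_6, so its rise depends on a signal near the floor. Among features with a symbol, ACP5 fell most, at -2.56 ± 0.14 (adjusted p 8.45e-12). PRAM1 followed at -2.29, then RBM20 at -2.12, RUNX1T1 at -2.12, JPH4 at -1.95 and DMTN at -1.95. Probes of RBM20 went opposite ways, and the other probe of DMTN was at -0.25.

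After 24 h with EPO, 10093 features differed with TNF (4667 higher, 5426 lower). Of them, 92.9% moved the same way on both direct arrays, a share that choosing them by the fit favours. A dye term per replicate left 5202, 4695 of them shared, and turned the balance to 56.3% higher. UBD was higher by 8.08 ± 0.30, BIRC3 by 4.14, TNFRSF9 by 3.59, CD70 by 3.37, LTB by 3.27 and TIMP3 by 3.09. COL21A1 changed by -3.25 ± 0.09 (adjusted p 3.98e-16), GYPB by -2.83, ACP5 by -2.51, CD40LG by -2.15, RUNX1T1 by -2.15 and GADD45G by -2.13 (its other probe -0.59). After 48 h the count was 5180 (2243 higher, 2937 lower), or 1736 with a dye term per replicate (1456 shared), when 64.3% were higher. With median centring 34.7% were higher at 24 h and 18.6% at 48 h, so the balance is not settled at these hours either. The correlation across genes between the direct arrays of A and C was 0.16 at 48 h, 0.47 at 6 h and 0.52 at 24 h. UBD rose by 5.72 ± 0.29 and PRG2 by 3.24 ± 0.18 at 48 h, ahead of CD70 (2.78), LTB (2.73), BIRC3 (2.69) and TNFRSF9 (2.40). Among features with a symbol, the falls at 48 h were led by COL21A1 (-2.64), RUNX1T1 (-2.16) and IHH (-2.13). NTRK3 (-1.77, with a probe at -0.15), GYPB (-1.72) and HLA-DOA (-1.66, with probes of opposite direction) came next.

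**Figure D2:**
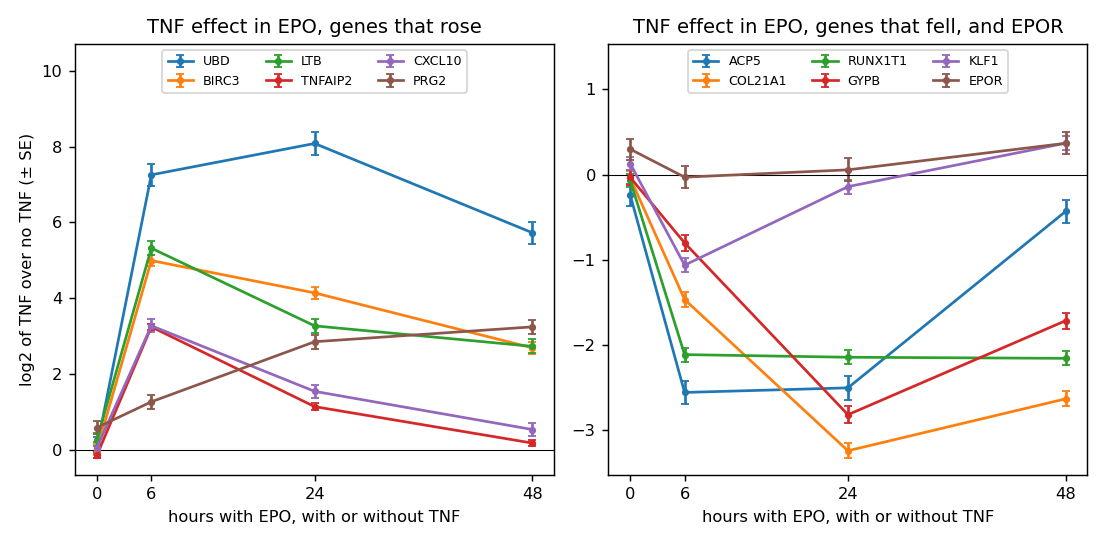
Log2 ratio of TNF over no TNF in EPO (vertical axis) against the hours of culture (horizontal axis) for genes that rose (left) and for genes that fell at some hour, with EPOR (right), with bars of ± SE from the fit of all arrays. UBD peaks at 24 h with 8.08 and is at 5.72 at 48 h, while RUNX1T1 stays between -2.16 and -2.12 from 6 h on, EPOR was at -0.03 at 6 h, and the genes drawn were chosen after their values were seen.

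**Figure D3:**
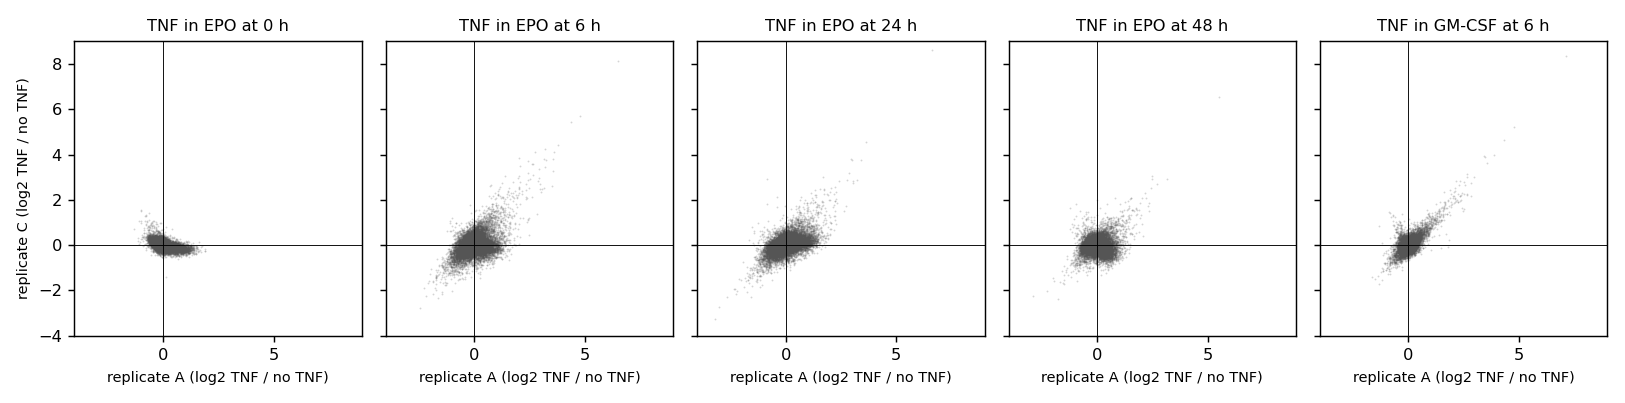
Each point is a gene with a symbol, at its log2 ratio of TNF over no TNF on the direct array of replicate A (horizontal) and of replicate C (vertical), in a panel for each pair. The 0 h panel slopes the opposite way to the others, and over all features the correlations were -0.46 at 0 h, 0.47 at 6 h, 0.52 at 24 h, 0.16 at 48 h and 0.59 in GM-CSF.

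With GM-CSF in place of EPO, TNF changed 2736 features at 6 h (1614 higher, 1122 lower). Of them, 99.4% moved the same way on both direct arrays, a share that choosing them by the fit favours. With a dye term per replicate the count was 1504, 1311 of them shared, and 76.1% were higher. The share of higher features was 59.0% in the fit of all arrays and 54.4% with paired extract means. UBD rose by 7.53 ± 0.31, BIRC3 by 4.84 ± 0.16, LTB by 4.18, TNFRSF9 by 3.82, TNFAIP2 by 3.75 and CD70 by 3.69. PLEKHA6 fell by 1.53, WNT11 by 1.41, ACP5 by 1.40, IHH by 1.38, SPNS2 by 1.35 and IRF5 by 1.21. Of features past the threshold in both cytokines at 6 h (2326), 1330 were higher in both and 959 lower in both, where chance gives 218 and 177. The 2 contrasts share no RNA, and their effects correlated across genes at 0.78. They do share the dye order of their direct arrays, so a dye bias of a replicate could add to that correlation.

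Tested as a difference, the TNF effect was not the same in GM-CSF and EPO for 1935 features, 1362 higher and 573 lower in GM-CSF. The count was 170 with paired extract means (78 higher) and 109 with median centring, and without replicate A it was 1310, with 634 higher and 676 lower, so the balance of directions depends on replicate A. The difference was 1.41 ± 0.12 for PRAM1, 1.46 for RBM20, 1.30 for TUBB1, 1.23 for LINC00173 and 1.17 for ACP5. It was -1.41 ± 0.12 for TIMP3, -1.37 for CXCL8, -1.33 for SPP1 and -1.22 for CD44. With paired extract means, TUBB1 (0.97, adjusted p 0.146), ACP5 (1.01, adjusted p 0.112) and SPP1 (-1.51, adjusted p 0.0544) did not pass, nor did CXCL8 with direct arrays only (-1.37, adjusted p 0.0604). Between 48 h and 6 h in EPO, the TNF effect differed for 5143 features, 2705 higher and 2438 lower at 48 h. It fell to 1579 with median centring and 1993 with paired extract means. SPP1 changed most, by -3.73 ± 0.20, then TNFAIP2 by -3.07, CD69 by -2.97 and TNFSF10 by -2.82. GALNT14 was higher by 2.25 ± 0.13, ACP5 by 2.13 (its effect at 48 h was -0.43, and changed sign with a dye term per replicate) and PRG2 by 1.98.

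Within a replicate, arrays joined 0 h to later hours in EPO only in B. The SEs of these contrasts therefore do not measure how the changes vary between replicates. Hours in EPO without TNF changed 352 features by 6 h, 1361 by 24 h and 3335 by 48 h, each against 0 h. With median centring these were 44, 114 and 577, without a dye term 141, 413 and 1588, and with separate channels 1304, 3143 and 5720. OSM rose by 2.37 ± 0.09, 2.76 and 2.55, and ID1 by 1.56, 2.03 and 2.22 in that order, but the other OSM probe was at only 0.19, 0.38 and 0.38. PIM1 rose by 1.79 at 6 h. BEX1 rose by 2.67 ± 0.14 and AQP1 by 2.38 at 48 h (its other probe 0.55). Metallothionein genes made up the 6 largest falls with a symbol at 6 h, with large errors. MT2A was at -1.43 ± 0.29 at 6 h (adjusted p 0.0138), -2.68 at 24 h and -2.63 ± 0.29 at 48 h. At 6 h MT2A did not pass in 6 of 20 alternatives, and with paired extract means it was at -0.86 (adjusted p 0.441). S100P was at -2.63 ± 0.12 at 48 h. In EPO plus TNF, again joined within replicate B only, 7799, 7751 and 6555 features differed from 0 h at 6, 24 and 48 h. With median centring these counts were 3808, 3634 and 2242. UBD led each of these contrasts, with 7.42, 8.62 and 5.81. By 48 h CHAC1 was higher by 3.76 ± 0.14 (its other probe 1.86) and PSAT1 by 2.99, and COL21A1 was at -3.41.

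GM-CSF and EPO without TNF differed at 6 h in 4719 features, 2441 higher and 2278 lower in GM-CSF, or 1377 with median centring and 2248 without a dye term. No array compared this pair directly, and within a replicate it was joined only in B, through 0 h. The same holds for the pair with TNF in both arms. The SEs of both pairs therefore do not measure how the differences vary between replicates. SLA was higher by 2.62 ± 0.11, NTS by 2.10, GP6 by 1.81 and PLK2 by 1.81, whereas COL21A1 was lower (-2.12 ± 0.13), as were LGALS3 (-1.79), TP53INP1 (-1.75) and KLHL24 (-1.73). With TNF in both arms, 1528 features differed, SLA by 1.92 ± 0.11, NTS by 1.57 and RNASE1 by -1.52. This count was 3313 with a dye term per slide and 156 with median centring.

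Among the gene lists, NF-kB feedback rose with TNF, with 22 of 25 members higher at 6 h in EPO (23 adjusted over the list alone) and a median of 0.90. The median of this list was 0.72 at 24 h, 0.23 at 48 h and 0.76 in GM-CSF, and camera passed each time (adjusted p 1.76e-23 at 6 h, 3.57e-05 with an estimated correlation). RELB rose by 3.74 and TNFAIP3 by 3.50 at 6 h. Cytokines, chemokines and adhesion had 25 of 31 members higher at 6 h (26 adjusted over the list alone), with a median of 1.20 at 6 h, 0.41 at 24 h and 0.12 at 48 h, where the adjusted p with an estimated correlation was 0.0940. CXCL11 rose by 3.61 and TNFSF10 by 3.32 at 6 h. Antigen presentation had 11 of 19 members higher at 6 h (13 adjusted over the list alone), TAP1 by 2.20. Immediate early genes had 23 of 32 higher (23 adjusted over the list alone), KLF6 by 2.75 (its other probe 0.10). JAK-STAT5 targets had 14 of 22 higher at 6 h (15 adjusted over the list alone), IL2RA by 3.03 (its other probe 1.47). Interferon response had a median of 0.07 at 6 h, where camera's adjusted p of 0.0473 became 0.231 with an estimated correlation, and of 0.32 at 24 h (0.00762 with an estimated correlation), when 19 of 33 members were higher (19 adjusted over the list alone).

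Erythroid regulators fell with TNF in EPO at 6 h, with 25 of 37 members lower (27 adjusted over the list alone), a median of -0.58 and an adjusted p of 1.67e-11 by camera (0.000906 with an estimated correlation). KLF1 was at -1.07 ± 0.08 at 6 h. At 48 h it was at 0.37, but did not pass without replicate A (0.16, adjusted p 0.331) or with a dye term per replicate (adjusted p 0.0715). GATA1, at -0.43 (adjusted p 0.0547), and EPOR, at -0.03 (adjusted p 0.894), did not pass at 6 h, and each moved opposite ways on the direct arrays of A and C. GATA1 passed in 13 of 22 alternatives, among them without replicate A (-0.85) and with a dye term per replicate (-0.68, adjusted p 0.00536). Without A, only arrays of C joined RNAs with TNF to those without. The fall of GATA1 thus stays open. The median of the list was -0.33 at 24 h and -0.02 at 48 h, where it did not pass (adjusted p 0.620). Globins and haem synthesis had 9 of 18 lower at 6 h (9 adjusted over the list alone) and 14 at 24 h (14 adjusted over the list alone), when ALAS2 was at -1.61 and HBD at -1.52. Both lists were also lower in GM-CSF than in EPO at 6 h, with medians of -0.58 and -0.59, and higher after 48 h in EPO than at 0 h, with medians of 0.18 and 0.47. JAK-STAT5 targets rose over 48 h in EPO, with 12 of 22 higher (13 adjusted over the list alone). The contrasts of hours in EPO and of GM-CSF with EPO were joined within replicate B only. For these and the lists below, their tests do not measure how the changes vary between replicates.

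Cholesterol synthesis rose with TNF at 6 h in EPO (21 of 27, 21 adjusted over the list alone), HMGCS1 by 2.46, with an adjusted p of 0.0457 with an estimated correlation. It was higher after 48 h in EPO (23 of 27, 25 adjusted over the list alone) and in GM-CSF against EPO (20, 22 adjusted over the list alone). With an estimated correlation its adjusted p was 0.0523 for TNF at 24 h, 0.385 at 48 h and 0.0748 in GM-CSF. Amino acid and ER stress rose with TNF, by a median of 0.58 at 6 h and 0.33 at 48 h. It passed camera at 24 h and in GM-CSF too, but with an estimated correlation the adjusted p was 0.212 and 0.0680. Hypoxia and glycolysis rose at 48 h (18 of 24, 18 adjusted over the list alone), VEGFA by 1.37, while at 6 h its adjusted p was 0.124 with an estimated correlation. Cell cycle passed camera in GM-CSF against EPO (17 of 39 higher, 21 adjusted over the list alone), but its adjusted p with an estimated correlation was 0.0748, and no contrast passed that way. The p53 list passed camera for TNF in GM-CSF alone (median 0.13), megakaryocyte markers for TNF at 48 h alone (median -0.19), and iron handling for 48 h in EPO alone (median 0.15), but fry passed in further contrasts for all 3 lists. Stem and progenitor genes fell with TNF at 48 h (median -0.10), and at 24 h the adjusted p with an estimated correlation was 0.0744. Lymphoid markers passed for TNF at 24 h (median 0.12), with an adjusted p of 0.245 with an estimated correlation. Monocyte and granulocyte genes passed in none of the 8 contrasts, with a smallest adjusted p of 0.0716 by camera and 0.0640 by fry. Of 152 list tests, 91 passed camera and 58 passed with an estimated correlation.

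**Figure D4:**
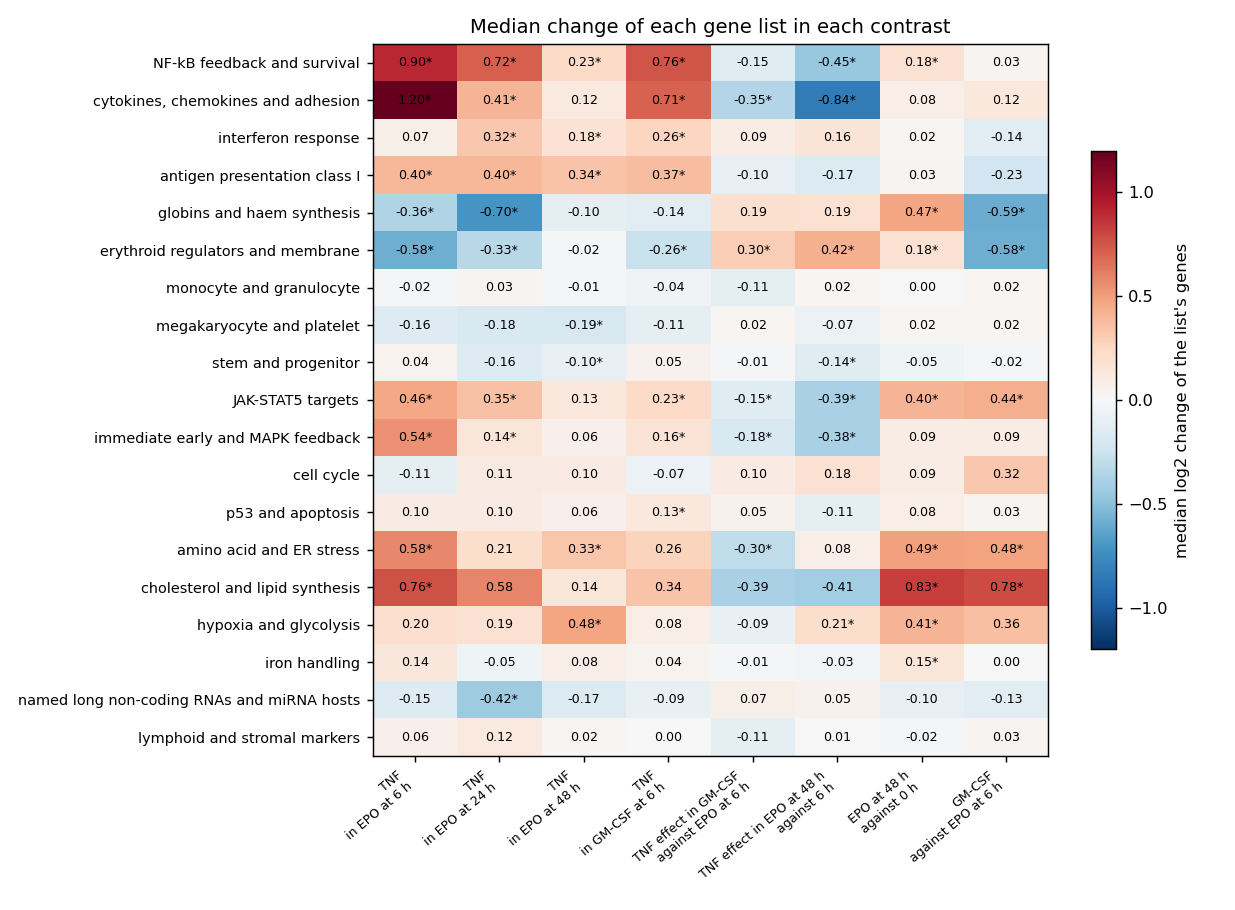
Median log2 change of the tested members of each of the 19 gene lists (vertical) in 8 contrasts (horizontal), with a star where camera passed with the preset and with the estimated correlation. NF-kB feedback has 0.90 for TNF in EPO at 6 h and 0.23 at 48 h, and erythroid regulators have -0.58 and -0.02.

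In the long non-coding class, 2183 of 10492 features changed with TNF at 6 h in EPO (20.8%), 710 higher and 1473 lower, against 33.6% of the other features. The class was dimmer, with a median log2 signal of 6.85 against 8.62. Its shares were 20.8% at 24 h, 10.0% at 48 h and 4.82% in GM-CSF. ENST00000517927 rose most with TNF in all 4, by 4.15 ± 0.08 at 6 h (adjusted p 2.48e-18), 3.13 at 24 h, 2.88 at 48 h and 3.47 ± 0.09 in GM-CSF. On the direct arrays at 6 h it was at 3.80 in A and 4.33 in C. ENST00000430694 rose by 1.87 ± 0.10 at 6 h, but was well above background in only 2 of 6 channels of E_6. The largest falls at 6 h were those of TCONS_00017068 (-2.33 ± 0.12) and TCONS_00007864 (-2.15 ± 0.09). The files do not pair these identifiers with gene names. The RNA in the series title was not matched to a probe by an identifier, so no value is given for it. Among named long non-coding RNAs, 18 of 28 were lower with TNF at 24 h (18 adjusted over the list alone), with an adjusted p of 0.0456 with an estimated correlation, and NEAT1 was at -1.07 at 6 h.

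Near PTTG1, 8 genes were tested. PTTG1 was higher with TNF by 0.28 ± 0.08 at 6 h (adjusted p 0.00742), 0.11 at 24 h (adjusted p 0.336), 0.43 ± 0.08 at 48 h (adjusted p 0.000331) and 0.23 in GM-CSF (adjusted p 0.0928). On the direct arrays of 6 h it was at 0.01 in A and 0.36 in C, and the array of A thus shows almost no rise. At 6 h PTTG1 did not pass in 7 of 22 alternatives. At 48 h it did not pass without replicate C (0.31, adjusted p 0.0638) or with median centring (0.18, adjusted p 0.528). SLU7 was lower with TNF in EPO, at -0.54 ± 0.10 at 6 h, -0.62 at 24 h and -0.46 at 48 h, and at -0.09 in GM-CSF (adjusted p 0.796). Its fall at 6 h came mostly from replicate A, with -1.14 on the direct array of A and -0.16 on that of C. Without replicate A it was at -0.22 at 6 h (adjusted p 0.122) and -0.27 at 48 h (adjusted p 0.112), but still passed at 24 h (-0.37, adjusted p 0.0138), and with paired extract means SLU7 passed at none of these hours. FAM200C was at -0.61 ± 0.09 at 6 h, and at -0.38 without replicate A, where it still passed. FABP6 was at -0.31, but did not pass without replicate A (-0.14, adjusted p 0.283) or with a dye term per replicate (adjusted p 0.227).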

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

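The alternative settings in this part were planned, except the dye term per replicate, and so was the first comparison of replicates at 48 h. The other tests were chosen after the results they weigh were seen. For 6 tests, a first version was replaced after its own result had been seen, and the values of both versions are given because they do not all agree.

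The TNF effect differed between GM-CSF and EPO at 6 h by a test of the difference itself, for 1935 features. The count fell to 720 with direct arrays only, 894 without replicate C, 632 without a dye term, 170 with paired extract means, 109 with median centring and 9 with extract means without the block. It was 2440 with a dye term per replicate, 1841 of them shared, so its size is uncertain. List medians of this difference were -0.35 for cytokines, chemokines and adhesion, 0.30 for erythroid regulators, -0.15 for JAK-STAT5 targets, -0.18 for immediate early genes and -0.30 for amino acid and ER stress. Among single genes it was 1.46 for RBM20, 1.41 for PRAM1, 1.30 for TUBB1, 1.23 for LINC00173, 1.17 for ACP5 and 1.16 for LOC100131289. On the other side it was -1.41 for TIMP3, -1.37 for CXCL8, -1.33 for SPP1, -1.22 for CD44, -1.17 for DUSP5 and -1.14 for LTB. Of these 12, RBM20 and DUSP5 passed in every alternative (though probes of RBM20 went opposite ways), and LTB failed in 9 of 22. TUBB1 (0.97), ACP5 (1.01), LOC100131289 (0.67), SPP1 (-1.51) and LTB (-1.50) did not pass with paired extract means, nor CXCL8 with direct arrays only (-1.37).

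A smaller range of ratios on the GM-CSF arrays would shrink all TNF effects alike. The slope of the effect in GM-CSF on that in EPO was 0.931 over the NF-kB list and 0.386 over the 4977 features that fell in EPO, a gap of 0.545. Choosing the latter features by their effect in EPO favours such a gap, so this first test decides nothing. In the replacing test, features that rose or fell by at least 0.5 in EPO on the direct array of 1 replicate were measured in the other. The ratio of the mean effects in GM-CSF and EPO was higher for those that rose by 0.228 to 0.419, over both replicates and both ways of modelling the dye. The bound of 0.3 was not met throughout, so a common shrinkage stays open. A candidate explanation is that GM-CSF alone already held these genes on the TNF side. Over the 1016 features past the threshold without replicate B, 87.0% had the same sign for GM-CSF against EPO in replicate B as for TNF in EPO in replicates A and C. That share was 75.0% of features past the threshold for TNF in EPO at 6 h and 61.6% of all features. Both sides used ratios without dye correction. The array of E_6 with E_0 in B and that of E_6 with ET_6 in A were both on slide 1, with E_6 on Cy5. A dye effect of that slide would thus add to the agreement. The values fit this hypothesis, which was found and tested on the same data.

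The TNF effect in EPO differed between 48 h and 6 h for 5143 features, again by a test of the difference. The count fell to 3163 with direct arrays only, 2974 without a dye term, 1993 with paired extract means, 1579 with median centring and 789 with extract means without the block. List medians were -0.45 for NF-kB feedback, -0.84 for cytokines, chemokines and adhesion, 0.42 for erythroid regulators, -0.14 for stem and progenitor genes, -0.39 for JAK-STAT5 targets, -0.38 for immediate early genes and 0.21 for hypoxia and glycolysis. The effect was lower at 48 h for SPP1 (-3.73), TNFAIP2 (-3.07), CD69 (-2.97), TNFSF10 (-2.82), CXCL10 (-2.74) and HLA-DOA (-2.69). It was higher for GALNT14 (2.25), ACP5 (2.13), PRG2 (1.98), S100P (1.96), RBM20 (1.91) and TLDC2 (1.87). With processed signals CXCL10 was at -1.46 and did not pass (adjusted p 0.0862), the other probe of HLA-DOA was at -0.16, and probes of RBM20 went opposite ways.

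A smaller range of ratios on the 48 h arrays was tested with a first and a replacing test, and these came out opposite ways. In the first, 2.50% of 3880 features past the threshold at 6 h and for the difference had a larger effect at 48 h in the direction of 6 h, and 3783 had a smaller one, as a smaller range predicts. Choosing features past the threshold at 6 h favours that outcome. In the replacing test, 14.1% of features past the threshold at both hours (430 of 3051) had effects of opposite direction, which shrinkage cannot give, and with a dye term per replicate the share was 12.4% of 993. A smaller range is therefore not the whole cause and stays open as part of it. The slope of the 48 h effect on the 6 h effect was 0.438 in replicate A and 0.289 in replicate C over features past the threshold at 6 h, a choice that favours slopes under 1. For features chosen by their 6 h effect in 1 of these replicates and measured in the other, the mean effect at 48 h was 0.287 to 0.366 of that at 6 h, so neither of these replicates alone accounts for the difference. Hours of culture, which the design names, remain untested as a biological cause.

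The 0 h pair of E_0 and ET_0 differed more in replicate A, where the log2 ratios had an SD of 0.30, than in replicate C (0.16). A dye bias of the arrays of replicate A is a candidate explanation. The departure of the 0 h array of A from a fit of slides 2 and 3 correlated across genes at 0.67 with that of the array of E_48 and E_6 of A. That array shares no RNA with the 0 h array, but had the highest median net signal (205 in Cy3, 364 in Cy5). Departures also share the errors of the fit they are taken from, which can add to their correlation. The departures of the later TNF pairs of replicate A correlated with that of the 0 h array at 0.81, 0.78 and 0.82, and that of GT_6 with ET_0 at 0.82, but that of G_6 with GT_6 at only 0.37, with the smallest SD of these arrays (0.19). A bias shared equally by all arrays of replicate A is therefore argued against, and an unequal one stays open. A dye bias shared equally by all of slide 1 is argued against by the array of replicate B on that slide, at -0.17. The first version of that test gave -0.18 on the same array, so it adds no separate support. All other arrays of slide 1 were of replicate A, so an unequal bias of the slide stays open too.

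TNF already acting at 0 h is argued against by the NF-kB list, whose median on that array was -0.0606 over 25 genes. The first version of this test, a correlation across genes with the TNF effect at 6 h in replicate C, gave 0.0963 against a bound of 0.1, too close to the bound to weigh. For the ET_0 RNA of replicate A, the first test fitted a departure of that RNA: the difference between replicates A and B in GT_6 against ET_0 correlated with the 0 h array at 0.56. A dye bias of replicate A predicts that too, as ET_0 carried the same dye on both arrays. The replacing test found that the other array of ET_0 correlated with the 0 h array by only 0.00562 more than the highest of the later TNF pairs, which did not hold that RNA. A departure of ET_0 alone is thus argued against, but a part of it on top of the dye bias stays open. No other biological explanation was tested for this pair.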

How the results depend on the processing

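The dye terms per scan and per replicate and the fits without 1 or both of 2 arrays of replicate A were chosen after seeing the data. Counts are of features past the threshold, except for the PTTG1 neighbours, where they are gene and contrast pairs past it (26 of 120 in the fit of all arrays, over 8 genes and 15 contrasts). Only counts beyond 1.5 times the reported count, either way, are given, except that leaving out replicates or arrays is given as ranges. The cause was not tested except where stated. No filter, a stricter filter, the mean of all probes, arrays as independent, the deposited ratios, and leaving out 1 or both of those arrays left all 15 counts within 1.5 times.

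With median centring in place of loess they were 5683 for TNF in EPO at 6 h, 5185 for TNF in EPO at 24 h, 2724 for TNF in EPO at 48 h, 1088 for TNF in GM-CSF at 6 h, 109 for TNF effect in GM-CSF against EPO at 6 h, 1579 for TNF effect in EPO at 48 h against 6 h, 44 for EPO at 6 h against 0 h, 114 for EPO at 24 h against 0 h, 577 for EPO at 48 h against 0 h, 3808 for EPO plus TNF at 6 h against 0 h, 3634 for EPO plus TNF at 24 h against 0 h, 2242 for EPO plus TNF at 48 h against 0 h, 1377 for GM-CSF against EPO at 6 h, 156 for GM-CSF plus TNF against EPO plus TNF at 6 h and 10 for the PTTG1 neighbours. Without a dye term they were 6128 for TNF in EPO at 6 h, 5986 for TNF in EPO at 24 h, 2467 for TNF in EPO at 48 h, 1594 for TNF in GM-CSF at 6 h, 632 for TNF effect in GM-CSF against EPO at 6 h, 2974 for TNF effect in EPO at 48 h against 6 h, 141 for EPO at 6 h against 0 h, 413 for EPO at 24 h against 0 h, 1588 for EPO at 48 h against 0 h, 4765 for EPO plus TNF at 24 h against 0 h, 3808 for EPO plus TNF at 48 h against 0 h, 2248 for GM-CSF against EPO at 6 h, 417 for GM-CSF plus TNF against EPO plus TNF at 6 h and 10 for the PTTG1 neighbours. With a change of at least 1 on the log2 scale also required, which can only lower a count, the counts were 546 for TNF in EPO at 6 h, 399 for TNF in EPO at 24 h, 162 for TNF in EPO at 48 h, 255 for TNF in GM-CSF at 6 h, 39 for TNF effect in GM-CSF against EPO at 6 h, 367 for TNF effect in EPO at 48 h against 6 h, 36 for EPO at 6 h against 0 h, 81 for EPO at 24 h against 0 h, 129 for EPO at 48 h against 0 h, 724 for EPO plus TNF at 6 h against 0 h, 675 for EPO plus TNF at 24 h against 0 h, 415 for EPO plus TNF at 48 h against 0 h, 238 for GM-CSF against EPO at 6 h and 56 for GM-CSF plus TNF against EPO plus TNF at 6 h.

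With extract means and a replicate block (paired) they were 5155 for TNF in EPO at 6 h, 4363 for TNF in EPO at 24 h, 1600 for TNF in EPO at 48 h, 1631 for TNF in GM-CSF at 6 h, 170 for TNF effect in GM-CSF against EPO at 6 h, 1993 for TNF effect in EPO at 48 h against 6 h and 197 for EPO at 6 h against 0 h. Extract means without the replicate block gave 2678 for TNF in EPO at 6 h, 1908 for TNF in EPO at 24 h, 625 for TNF in EPO at 48 h, 809 for TNF in GM-CSF at 6 h, 9 for TNF effect in GM-CSF against EPO at 6 h, 789 for TNF effect in EPO at 48 h against 6 h, 54 for EPO at 6 h against 0 h, 465 for EPO at 24 h against 0 h, 833 for EPO at 48 h against 0 h, 4091 for EPO plus TNF at 6 h against 0 h, 4784 for EPO plus TNF at 24 h against 0 h, 2419 for EPO plus TNF at 48 h against 0 h, 2243 for GM-CSF against EPO at 6 h, 579 for GM-CSF plus TNF against EPO plus TNF at 6 h and 4 for the PTTG1 neighbours.

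A fit of separate channels gave 1304 for EPO at 6 h against 0 h, 3143 for EPO at 24 h against 0 h, 5720 for EPO at 48 h against 0 h, 7317 for GM-CSF against EPO at 6 h and 3634 for GM-CSF plus TNF against EPO plus TNF at 6 h. Direct arrays only, which are fewer arrays, gave 2786 for TNF in EPO at 48 h, 720 for TNF effect in GM-CSF against EPO at 6 h and 3163 for TNF effect in EPO at 48 h against 6 h. Processed signals gave 214 for EPO at 6 h against 0 h and 829 for EPO at 24 h against 0 h. Scaling between arrays gave 545 for EPO at 6 h against 0 h and 683 for GM-CSF plus TNF against EPO plus TNF at 6 h. A dye term per slide gave 2046 for EPO at 24 h against 0 h and 3313 for GM-CSF plus TNF against EPO plus TNF at 6 h. A dye term per scan gave 3156 for TNF in EPO at 48 h. A dye term per replicate gave 1 for TNF in EPO at 0 h, 5319 for TNF in EPO at 6 h, 5202 for TNF in EPO at 24 h, 1736 for TNF in EPO at 48 h, 1504 for TNF in GM-CSF at 6 h, 729 for EPO at 6 h against 0 h and 2273 for EPO at 24 h against 0 h. That term is hard to separate from the TNF effect, so lower counts of TNF effects with it can also mean lost precision.

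Leaving out each replicate, or 1 of those arrays of replicate A, in turn, which removes arrays, gave counts of 0 to 1578 for TNF in EPO at 0 h, 7512 to 9154 for TNF in EPO at 6 h, 6510 to 10055 for TNF in EPO at 24 h, 2958 to 6484 for TNF in EPO at 48 h, 1167 to 2700 for TNF in GM-CSF at 6 h, 894 to 2116 for TNF effect in GM-CSF against EPO at 6 h, 3314 to 5251 for TNF effect in EPO at 48 h against 6 h and 225 to 451 for EPO at 6 h against 0 h. It gave 1091 to 2027 for EPO at 24 h against 0 h, 2248 to 3957 for EPO at 48 h against 0 h, 6837 to 8793 for EPO plus TNF at 6 h against 0 h, 6879 to 9732 for EPO plus TNF at 24 h against 0 h, 5651 to 7532 for EPO plus TNF at 48 h against 0 h, 2740 to 6612 for GM-CSF against EPO at 6 h, 1141 to 1536 for GM-CSF plus TNF against EPO plus TNF at 6 h and 24 to 28 for the PTTG1 neighbours. The count of 0 h features was 1578 without replicate C. Without A or without C, RNAs with TNF are joined to those without in a single replicate with a single dye order. A dye bias of that replicate then cannot be told from a TNF effect. Without replicate B, no array joins the 0 h and GM-CSF RNAs, the 24 h RNAs and the 6 and 48 h EPO RNAs to each other, so contrasts between RNAs of different hours or cytokines have no value there, while differences of TNF effects do. A lone extract is then assumed to vary like the others. With a dye term per replicate the 0 h count was 1, and it was 0 in the other settings.

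The share of higher features moved with median centring from 46.1 to 25.1% for TNF in EPO at 6 h, 46.2 to 34.7% for TNF in EPO at 24 h, 43.3 to 18.6% for TNF in EPO at 48 h, 70.4 to 85.3% for TNF effect in GM-CSF against EPO at 6 h, 83.5 to 97.7% for EPO at 6 h against 0 h, 61.4 to 71.9% for EPO at 24 h against 0 h, 46.9 to 58.8% for EPO plus TNF at 24 h against 0 h, 51.7 to 68.4% for GM-CSF against EPO at 6 h and 72.5 to 88.5% for GM-CSF plus TNF against EPO plus TNF at 6 h. With a dye term per replicate it became 56.3% for TNF in EPO at 24 h, 64.3% for TNF in EPO at 48 h, 76.1% for TNF in GM-CSF at 6 h and 55.6% for GM-CSF plus TNF against EPO plus TNF at 6 h. Without replicate A it was 48.4% for TNF effect in GM-CSF against EPO at 6 h, 47.5% for GM-CSF plus TNF against EPO plus TNF at 6 h and 53.7% for TNF in EPO at 48 h. With paired extract means it was 45.9%, 62.0% and 65.5% for the same 3, and 43.1% for EPO at 48 h against 0 h (61.5% in the fit of all arrays).

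Limma's camera with an estimated correlation passed in 5 contrasts for cytokines, chemokines and adhesion, 3 contrasts for interferon response, 4 contrasts for globins and haem synthesis, 0 contrasts for cell cycle, 3 contrasts for cholesterol and lipid synthesis, 3 contrasts for hypoxia and glycolysis, 1 contrast for named long non-coding RNAs and miRNA hosts and 0 contrasts for lymphoid and stromal markers. Fry passed in 3 for megakaryocyte and platelet, 7 for stem and progenitor, 4 for p53 and apoptosis, 3 for iron handling, 3 for named long non-coding RNAs and miRNA hosts and 2 for lymphoid and stromal markers. Of 140 gene and contrast pairs past the threshold that the text names or draws, 25 did not pass in some alternative (the one on the size of the change aside), 8 of them in 5 or more. ACP5 for TNF in EPO at 48 h changed sign with a dye term per replicate, to 0.042 from -0.43. EPOR for TNF in EPO at 24 h went from -0.34 without replicate A to 0.32 without replicate C, and did not pass in the fit of all arrays (0.06). Signal over background limits genes dim in 1 arm.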

Other observations

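The splits were set before the results were seen, and the comparisons of effects between contrasts were chosen after. Each count was compared with other splits of the 6 RNAs of a contrast, or of 6 TNF effects for a difference of effects. The 10 splits cannot give a share under 0.05, so only the real count and the highest other are given. The real count and the highest other were 9240 and 0 for TNF in EPO at 6 h, 10093 and 467 for TNF in EPO at 24 h, 5180 and 4 for TNF in EPO at 48 h, 2736 and 1 for TNF in GM-CSF at 6 h and 1935 and 3 for TNF effect in GM-CSF against EPO at 6 h. They were 5143 and 0 for TNF effect in EPO at 48 h against 6 h, 352 and 0 for EPO at 6 h against 0 h, 1361 and 0 for EPO at 24 h against 0 h, 3335 and 63 for EPO at 48 h against 0 h and 7799 and 2694 for EPO plus TNF at 6 h against 0 h. The last 4 contrasts had 7751 and 199 for EPO plus TNF at 24 h against 0 h, 6555 and 2995 for EPO plus TNF at 48 h against 0 h, 4719 and 0 for GM-CSF against EPO at 6 h and 1528 and 7 for GM-CSF plus TNF against EPO plus TNF at 6 h. In each of these, 1 of 10 splits, the real one, gave a count as large. Other splits mix the groups, and a real difference then widens their residuals. Their counts are therefore not those of data without a difference. For TNF in EPO at 0 h the real count was 0 by limma, with 3727 features at an unadjusted p under 0.05, and the highest other was 1. There 10 of 10 splits gave at least as many, which a real count of 0 makes certain, so the splits say nothing about that pair.

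Effects of TNF at 6 and 24 h in EPO correlated across genes at 0.76 against 0.16 in simulated data without any change, with 5749 features past the threshold in both. The departures of their direct arrays in replicate A correlated with that of the 0 h array at 0.81 and 0.78. A dye bias shared by those arrays could add to the 0.76. For TNF at 6 h and GM-CSF against EPO, 2932 features passed in both, 88.5% in the same direction, with a correlation of 0.40 against 0.25. For EPO at 48 h against 0 h and GM-CSF against EPO these were 1569, 87.6% and 0.37 against -0.43. TNF at 6 h and GM-CSF against EPO share the E_6 RNA, which adds to their 88.5%. For them 1117 features were higher in both and 1477 lower in both, where independent contrasts give 330 and 360. EPO at 6 h and at 48 h, each against 0 h, correlated at 0.65, where simulated data that share the E_0 RNA gave 0.67, but with a covariance of 0.0176 against 0.00686. All 302 features past the threshold in both moved the same way, 256 higher and 46 lower, where independent contrasts give 19.1 and 2.36, and the shared E_0 RNA adds to that.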
